A study of Sus scrofa with 6 samples.

How the data were processed

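Backfat of male pigs was measured on 6 Affymetrix Porcine expression arrays, 3 from intact males (boars) and 3 from castrated males (barrows). Per the labels' protocols, 15 pairs of full brothers from Pietrain sires and Landrace dams entered the study, and in each pair 1 piglet was castrated at 7 days of age. The 30 animals were weaned at 30 days, fed freely and killed at 175 days, and the middle layer of backfat at the 6th rib was frozen. RNA was isolated with a Qiagen lipid tissue kit, and equal amounts from 5 animals of 1 kind were combined into each of the 6 pools. Each pool was labelled from 5 µg of total RNA and put on an array of its own. A replicate is therefore a pool of 5 animals, and p-values measure the spread between pools, not between single pigs.

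The deposited table holds 1 signal intensity per probe set and array on a linear scale. Per the submitters' processing notes these intensity values came from MAS5, the Affymetrix summary of perfect-match and mismatch probes. Its version and settings are not given in the sources used here. As tested on the values, the 2% trimmed mean of every array was close to 500 (500.09 to 500.10), which points to a global scaling by the authors, and no other normalization between arrays was visible. Median signals ran from 162 to 173. Detection calls were not used here, so it is unknown which probe sets stood above background, and the number of arrays limits the precision. MAS5 signals of dim probe sets are noisy, and the highest signal on an array was 27591 to 32517, and differences among the brightest probe sets can be compressed.

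Of the 24123 probe sets, 10099 had 1 gene symbol in the platform annotation, 198 had several and 13826 had none. The symbol of 9989 was found again through its gene identifier in the RefSeq table (assembly Sscrofa11.1), and 0 symbols changed. Probe sets with several symbols or none were tested but not named. The array carries no genome build, so no coordinates are given. The 124 control probe sets were left out, which left 23999.

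The values were kept at the authors' scaling and transformed to log2(signal + 16). The 14399 probe sets in the upper 60% by mean over all 6 arrays were tested, which corresponds to a mean signal of about 92.7 or more. Barrow was compared with boar by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences and folds refer to log2(signal + 16), which understates changes of dim genes. Confidence intervals are 95% intervals of that model.

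Gene lists were written before the data were examined. Each of the 33 lists was tested with limma's camera at a preset correlation of 0.01 where at least 5 members passed the filter. This held for 29, with adjustment over those 29. A gene was represented by its brightest tested probe set, which gave 5356 genes. Members were also adjusted over the list alone. The lists were also tested by camera with a correlation estimated from the data and by fry, which tests whether the members of a list move on balance in 1 direction without comparing them with other genes. RNA quality was examined by an exact permutation test of 3'/5' signal ratios of actin and GAPDH control probe sets.

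Named genes followed a rule fixed before the data were examined. It took (a) per direction the 12 genes with the largest difference among those past the threshold whose groups did not overlap, (b) up to 4 members per list with the smallest unadjusted p, and (c) 22 genes of fat metabolism and steroid action wherever they were tested. It named 157 genes, of which 37 passed the threshold. ACLY and PLIN1 were not analysed here because no probe set carried that symbol, and SREBF1 fell below the filter. 1 item is not reported here.

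Both groups carry replicate numbers 1 to 3, and the design text says that the pools of a kind were formed from the sib pairs without stating that a number marks the same families. The residuals of boar and barrow pools with the same number correlated at 0.12, 0.17 and 0.26, against -0.19 to -0.01 for other combinations. All 3 values exceed the minimum of 0.1 set beforehand, so the numbers were taken to pair the pools. The residuals were centred within each group, which by itself pushes other combinations below 0 when these 3 lie above it. The contrast is therefore not separate evidence, and what the numbers share was not tested. The comparison is given without a block, as planned, and for the genes described below the blocked value stands beside it where it changes a call.

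On simulated arrays with the real means and residual spreads of this comparison (14399 probe sets, 200 of them changed), 20 of 67 probe sets changed by 0.5 on the log2 scale were called, 52 of 67 changed by 1 and 66 of 66 changed by 2. Of the unchanged probe sets 6 were called, and 0 were called when nothing had been changed. A list shifted by 0.3 was called and none of the other 28 lists was (5356 genes). Probe sets were simulated as independent of each other, so the simulation cannot show how correlated genes affect the list calls. Alternatives covered the pseudocount (1 and 64), the filter (none, and the upper 40%), quantile normalization, a median shift, eBayes without the trend, array weights, the replicate block, each array left out in turn, other thresholds, other list tests, and the mean of a gene's probe sets in place of the brightest.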

Results

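The study asked how castration alters gene expression in the subcutaneous fat of male pigs. Boars, which keep their testes, were compared with barrows, their castrated full brothers, at 175 days of age. There were 2 groups of 3 arrays, each array measuring a pool of backfat RNA from 5 pigs, and 14399 probe sets were compared. Between arrays of a group the log2 signals correlated at 0.978 to 0.988, and between groups at 0.975 to 0.983. The first principal component held 31.6% of the variance and the second 26.6%, with barrow replicate 2 at the far end of the first. The RNA quality controls overlapped between the groups: the log2 3'/5' ratio of actin was 2.03 ± 0.08 in boars (SD, n = 3) and differed by -0.03 in barrows (exact permutation p = 0.8), and that of GAPDH was 1.31 ± 0.06 and 1.28 ± 0.18 (exact permutation p = 0.8). With 3 against 3 arrays this test cannot give a p below 0.1.

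In barrow fat 167 probe sets changed, 101 higher and 66 lower than in boar fat (limma, adjusted p under 0.05). Among genes with a symbol, the rise was led by PIP, C1QTNF3, the interferon-induced genes ISG15 and RSAD2, UCHL1 and COMP, and the fall by the transcripts LOC100152327 and LOC396781, CYP2B22, complement C4A, SLC22A3 and SAL1. As lists, fatty acid synthesis, glycolysis and the interferon response were higher in barrows (camera adjusted p = 1.3e-04, 1.6e-04 and 1.6e-13), and complement and the markers of macrophages, endothelium and lymphocytes lower (adjusted p = 1.4e-06, 0.0032, 0.0035 and 0.022). With an estimated correlation 0 of the 29 lists tested passed (adjusted p = 0.44, 0.44 and 0.093, and 0.27, 0.40, 0.27 and 0.58, in the same order), and 2 of 11, 0 of 18 and 9 of 20 members rose and 2 of 16, 0 of 15, 1 of 15 and 0 of 10 fell. Changes were mostly modest, with a median absolute log2 difference of 0.64 among the 167 and at least a 2-fold difference in 20 of them, 10 in each direction. The changed probe sets covered 88 genes with a symbol, and 72 probe sets had no symbol. Among these, 1 probe set rose by 3.58 on the log2 scale, from a mean signal of 47.2 ± 9.85 to 796 ± 427 (SD, n = 3 each). Its boar mean log2, 5.97, lay below the lowest tested mean over all arrays, 6.76. It thus passed the filter only through its barrow signals. Another 2 had differences of -1.88 and -1.87, the largest falls of all, from 487 ± 88.8 to 128 ± 54.1 and from 392 ± 74.4 to 94.6 ± 14.2.

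The groups did not overlap in any of the 167 probe sets, nor in 2613 of all those tested (18.1%, where chance gives 10%), and 1753 had an unadjusted p under 0.05 where 720 are expected by chance. With the replicate number as a block 338 probe sets changed, 215 higher and 123 lower, and 166 of the 167 were among them. The count was 24 without boar replicate 1, 31 without boar replicate 3, 53 without barrow replicate 1, 66 without barrow replicate 3 and 291 without barrow replicate 2. All 167 kept their direction in each of these fits, which was fixed in advance because their groups do not overlap.

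**Figure D1:**
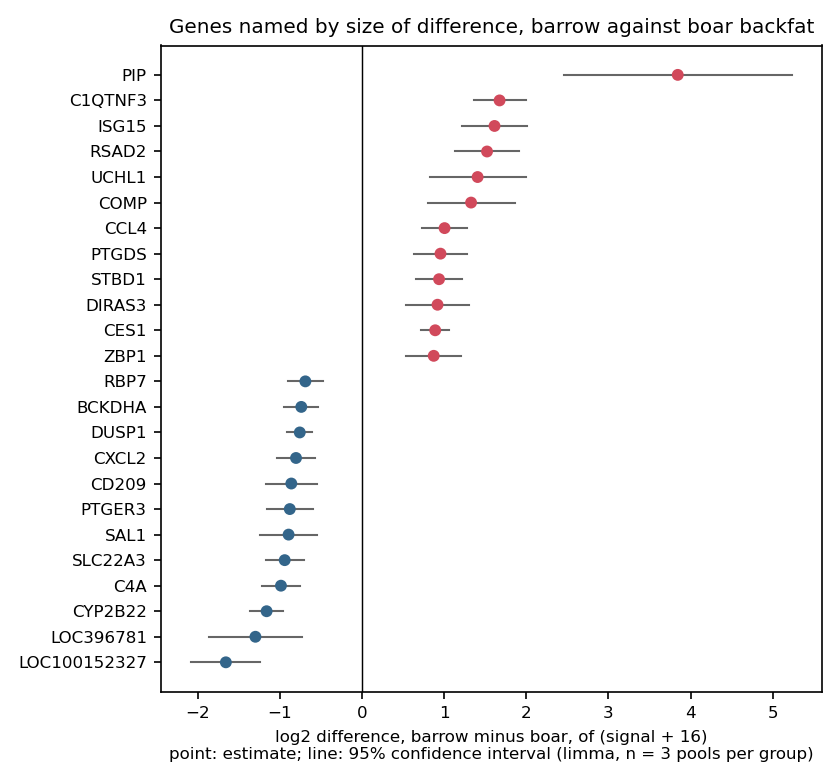
Log2 difference between barrow and boar backfat, in log2(signal + 16) with the zero line marked, for the 12 genes per direction chosen by size of difference. Points are limma estimates and lines 95% confidence intervals (n = 3 pools per group), from 3.84 for PIP to -1.66 for LOC100152327.

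Among the genes that rose, PIP, a protein secreted by sweat, salivary and mammary glands, had the largest difference, with a mean signal of 15.8 ± 13.1 in boars and 645 ± 748 in barrows (SD, n = 3 each). Its 3 barrow values were 207, 1508 and 219 and its boar values lay at or under 29.9, so the 14.4-fold estimate (95% CI 5.47 to 37.6, limma adjusted p = 0.018) depends on the pseudocount, and with pseudocount 64 the log2 difference was 2.64 against 3.84. The mean log2 of PIP in boars, 4.91, lay far below the lowest tested mean over all arrays, 6.76. PIP thus passed the filter only through its barrow signals, and its boar signals are not shown to exceed background. The call was lost without boar replicate 1 (adjusted p = 0.098), without boar replicate 3 (adjusted p = 0.065), without the intensity trend (adjusted p = 0.11) and without a filter (adjusted p = 0.052). C1QTNF3, a secreted protein of the adiponectin family, rose 3.19-fold (95% CI 2.56 to 3.98, adjusted p = 5.9e-04). UCHL1, a deubiquitinating enzyme abundant in neurons, rose 2.65-fold (adjusted p = 0.035) and COMP, a matrix protein of cartilage and tendon, 2.51-fold (adjusted p = 0.029). The mean log2 of COMP in boars, 6.66, also lay below the lowest tested mean, and that of UCHL1, 6.76, lay at it. Their boar signals are likewise not shown to exceed background. The chemokine CCL4 rose 2.01-fold, prostaglandin D2 synthase PTGDS 1.94-fold and the glycogen-binding protein STBD1 1.92-fold. DIRAS3, a small GTPase, rose 1.89-fold, the carboxylesterase CES1 1.85-fold (from 4155 ± 276 to 7718 ± 501) and the nucleic acid sensor ZBP1 1.83-fold.

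Among the genes that fell, LOC100152327, which has no other name in the RefSeq table, was 3.15-fold higher in boars (95% CI 2.36 to 4.22, adjusted p = 0.0030). LOC396781, which the RefSeq table (Sscrofa11.1) lists with the synonym IGHG, an immunoglobulin heavy chain name, was 2.46-fold higher in boars (95% CI 1.66 to 3.63, adjusted p = 0.040). The cytochrome P450 CYP2B22 was 2.24-fold higher in boars (2906 ± 61.3 against 1295 ± 131) and the organic cation transporter SLC22A3 1.92-fold. SAL1, the salivary lipocalin that carries boar pheromones, was 1.86-fold higher in boars (7049 ± 1775 against 3701 ± 218, adjusted p = 0.026). The prostaglandin E receptor PTGER3 was 1.84-fold higher in boars, the lectin CD209 of dendritic cells and macrophages 1.82-fold and the chemokine CXCL2 1.75-fold. DUSP1, a phosphatase of MAP kinases, was 1.69-fold higher in boars, BCKDHA, an enzyme of branched-chain amino acid breakdown, 1.67-fold, and RBP7, a retinol-binding protein, 1.61-fold.

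Genes of fatty acid synthesis were higher in barrows as a list (mean log2 difference 0.27, 20.5%, camera adjusted p = 1.3e-04, and adjusted p = 0.44 with an estimated correlation). Of 11 tested members 2 rose over all probe sets, 6 when adjusted over the list alone, 5 with the replicate block, and 0 fell. Malic enzyme ME1 rose 1.36-fold (95% CI 1.20 to 1.54, adjusted p = 0.028) and fatty acid synthase FASN 1.27-fold (95% CI 1.15 to 1.40, adjusted p = 0.035, from 13165 ± 687 to 16680 ± 744). Neither call was kept under every alternative, where the limma adjusted p ran up to 0.18 for ME1 and 0.23 for FASN. PGD, of the pentose phosphate pathway, was 1.40-fold higher with an adjusted p of 0.065 (0.0081 with the replicate block), and ACSS2, which makes acetyl-CoA from acetate, was 1.34-fold higher with an adjusted p of 0.092 (0.020 with the block). The desaturase SCD had a log2 difference of 0.12 (adjusted p = 0.55) between high mean signals of 22358 and 24292, and ACACA had 0.39 (adjusted p = 0.55). The elongase ELOVL6 had 0.22 in its brightest probe set (adjusted p = 0.18), while its 3 other probe sets rose by 0.81, 0.83 and 0.96 on the log2 scale (adjusted p from 5.9e-04 to 0.0018). The other probe set of ME1 rose by 0.75, and the 2 other probe sets of FASN had 0.86 and 0.95 (adjusted p = 0.097 and 0.10, and 0.0025 and 0.0073 with the replicate block). With the mean of probe sets FASN had 0.72 (adjusted p = 0.045) and ELOVL6 0.70 (adjusted p = 8.4e-04).

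**Figure D2:**
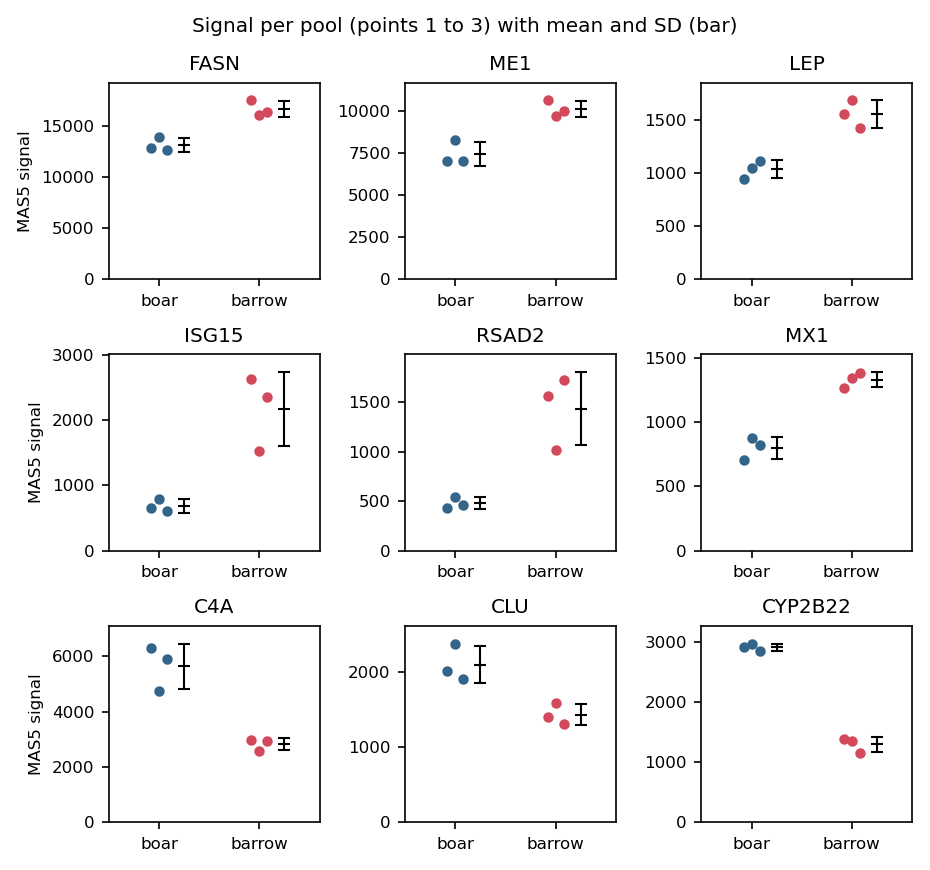
Deposited MAS5 signal of 9 named genes in each of the 3 boar and 3 barrow pools (points, linear axis from 0), with mean and SD as a bar. The barrow pools of FASN average 16680 against 13165 in boars, and those of C4A 2828 against 5650.

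Triacylglycerol synthesis and lipid droplet genes did not pass as a list (mean 0.06, adjusted p = 0.46), with 0 of 12 members past the threshold. DGAT2 had a log2 difference of 0.11 (adjusted p = 0.59). Lipolysis genes did not pass either (mean 0.07, adjusted p = 0.80), although 1 of 9 members, CES1, rose, and with the replicate block 2 others fell. The lipases LIPE and PNPLA2 had differences of 0.13 (adjusted p = 0.66) and -0.06 (adjusted p = 0.77), and another probe set of PNPLA2 went the other way. AQP3, a glycerol channel, had -0.34 (adjusted p = 0.061, and 0.031 with the replicate block) and ABHD5, the activator of PNPLA2, had -0.40 (adjusted p = 0.10, and 0.029 with the block).

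Fatty acid oxidation genes were higher in barrows as a list (mean 0.11, adjusted p = 0.030, and adjusted p = 0.58 with an estimated correlation), with 0 of 20 members past the threshold, 3 when adjusted over the list alone and 2 with the replicate block. The matrix enzymes ECHS1 and ECI1 had 0.35 and 0.33 (adjusted p = 0.071 and 0.096, and 0.018 and 0.037 with the block), and CPT1A, which admits fatty acids to mitochondria, had -0.09 (adjusted p = 0.75). The call was lost under quantile normalization (0.10, adjusted p = 0.064), with array weights (0.09, adjusted p = 0.089), with the mean of probe sets (0.08, adjusted p = 0.14), without boar replicate 1 (0.10, adjusted p = 0.066) and without barrow replicate 2 (0.07, adjusted p = 0.21), and without a filter the mean was 0.20 (adjusted p = 0.0059).

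Glucose uptake and glycolysis genes were higher in barrows (mean 0.18, adjusted p = 1.6e-04, and adjusted p = 0.44 with an estimated correlation), with 0 of 18 members past the threshold, 7 when adjusted over the list alone and 3 with the replicate block. HK1 had a log2 difference of 0.42 and PGK1 of 0.32 (adjusted p = 0.062 and 0.078, and 0.036 and 0.029 with the block). Citrate cycle genes were higher (mean 0.11, adjusted p = 0.010, and adjusted p = 0.58 with an estimated correlation), with 17 of 20 members above 0, 0 past the threshold and 2 past it with the replicate block, and SDHA at 0.30 (adjusted p = 0.067, and 0.040 with the block). Their call was lost without barrow replicate 2 (0.07, adjusted p = 0.11). Oxidative phosphorylation genes were higher by little (mean 0.08, adjusted p = 0.0099, and adjusted p = 0.76 with an estimated correlation), with 32 of 38 members above 0 and none past the threshold. That call was lost with array weights (0.06, adjusted p = 0.079), without barrow replicate 2 (0.03, adjusted p = 0.29) and without boar replicate 3 (0.06, adjusted p = 0.070).

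The interferon response list had the greatest mean difference of the 29 lists tested (0.51, adjusted p = 1.6e-13, and adjusted p = 0.093 with an estimated correlation). Of 20 members 9 rose over all probe sets, 12 when adjusted over the list alone, and 0 fell. ISG15, a ubiquitin-like protein, rose 3.06-fold (95% CI 2.32 to 4.03, adjusted p = 0.0027, from 685 ± 100 to 2167 ± 566), and the antiviral enzyme RSAD2 2.87-fold (95% CI 2.19 to 3.77, adjusted p = 0.0032). The RNA sensor DDX58 rose 1.70-fold and the antiviral GTPase MX1 1.66-fold. Averaged over the list, the log2 signal was 9.32 ± 0.04 in boars and 9.83 ± 0.06 in barrows (SD, n = 3 each). The macrophage marker list had a mean of -0.18, as given next.

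Complement genes were lower in barrows (mean -0.31, adjusted p = 1.4e-06, and adjusted p = 0.27 with an estimated correlation), with 15 of 16 members below 0. C4A fell, at 1.98-fold higher signal in boars (95% CI 1.68 to 2.33, adjusted p = 0.0025), as did the chaperone CLU at 1.46-fold (adjusted p = 0.039, and up to 0.16 under the alternatives), and 7 members fell when adjusted over the list alone and 4 with the replicate block. C1S had a log2 difference of -0.29 (adjusted p = 0.053, and 0.030 with the block) and C1QA, which macrophages make, -0.44 (adjusted p = 0.13, and 0.035 with the block). Macrophage markers were lower (mean -0.18, adjusted p = 0.0032, and adjusted p = 0.40 with an estimated correlation), with 13 of 15 below 0 and 0 past the threshold. With the replicate block 1 passed, C1QA, which like C1QC is also in the complement list. TYROBP had -0.39 (adjusted p = 0.14). Endothelial markers were lower by the same mean (-0.18, adjusted p = 0.0035, and adjusted p = 0.27 with an estimated correlation), with 13 of 15 below 0, and the angiopoietin receptor TEK fell (1.39-fold higher in boars, adjusted p = 0.047, and up to 0.25 under the alternatives). Its other probe set had -0.20 (adjusted p = 0.73). Lymphocyte markers were lower (mean -0.15, adjusted p = 0.022, and adjusted p = 0.58 with an estimated correlation), with 9 of 10 below 0, but that call was lost without boar replicate 1 (-0.08, adjusted p = 0.11), without boar replicate 3 (-0.09, adjusted p = 0.097) and without barrow replicate 1 (-0.13, adjusted p = 0.096), and without boar replicate 2 the mean was -0.30 (adjusted p = 0.0025). Smooth muscle and pericyte markers (mean 0.01, adjusted p = 0.88) and stromal progenitor and fibroblast markers (mean -0.02, adjusted p = 0.80) did not pass. Only with the replicate block did KCNJ8 (-0.49, limma adjusted p = 0.048) and DPT (-0.32, limma adjusted p = 0.041) fall and FBLN1 (0.50, limma adjusted p = 0.047) rise.

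**Figure D3:**
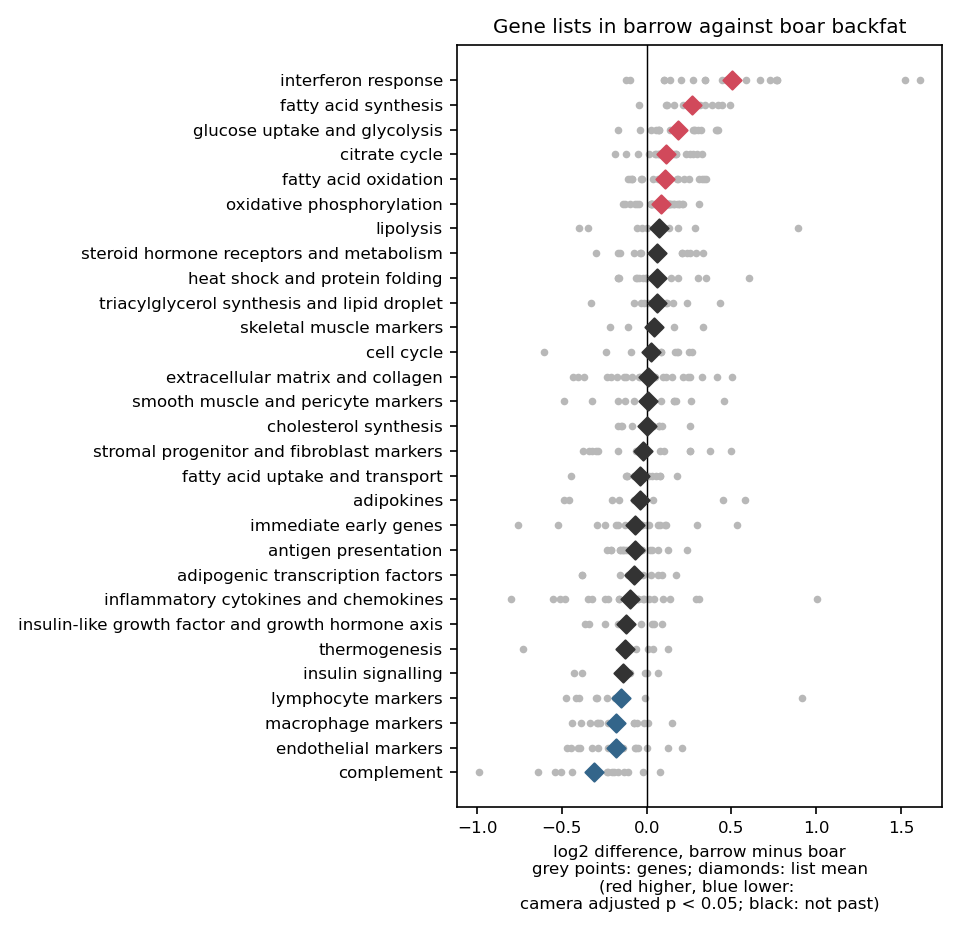
Log2 difference between barrow and boar backfat for the tested genes of each of the 29 tested lists (grey points) and the list mean (diamonds, coloured where the camera adjusted p was under 0.05). The means run from 0.51 for the interferon response to -0.31 for complement.

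Single genes changed in lists that did not pass. Among the adipokines (mean -0.04, adjusted p = 0.83) leptin, LEP, rose by 0.58 on the log2 scale (95% CI 0.37 to 0.80, adjusted p = 0.021, from 1036 ± 84.9 to 1559 ± 130, with 0.45 and adjusted p = 0.24 in its other probe set) and angiotensinogen, AGT, 1.37-fold (adjusted p = 0.012), while ADIPOQ had -0.07 (adjusted p = 0.76). Under the alternatives the limma adjusted p ran up to 0.14 for both LEP and AGT. Dimmer leptin control probe sets, outside the comparisons, had -0.08 and 0.12 (boar means 281 and 247, exact permutation p = 0.8 and 0.9). RBP4 had -0.46 (limma adjusted p = 0.12, and 0.013 with the replicate block). Among inflammatory cytokines and chemokines (mean -0.10, adjusted p = 0.14, but 0.017 in the upper 40% and 0.024 without boar replicate 2) CCL4 rose, and CXCL2 and CCL19 fell, the last at 1.47-fold higher signal in boars. Among extracellular matrix genes (mean 0.01, median 0.03, adjusted p = 0.96, with the test pointing down) THBS2 rose 1.42-fold and LAMB1 fell (1.32-fold higher in boars, with -0.29 and adjusted p = 0.26 in its other probe set). CRYAB, a small heat shock protein, rose 1.52-fold in the heat shock list (mean 0.06, adjusted p = 0.41). Of the immediate early genes (mean -0.07, adjusted p = 0.18), which respond to tissue handling, DUSP1 and EGR1 fell, EGR1 at 1.44-fold higher signal in boars. The 2 other probe sets of EGR1 had -0.16 and -0.25 (adjusted p = 0.87 and 0.43), and with the mean of probe sets its call was lost (-0.31, adjusted p = 0.33).

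Other lists gave no call. Fatty acid uptake and transport had a mean of -0.04 (adjusted p = 0.74), with FABP4 at -0.11 and LPL at 0.03 (adjusted p = 0.61 and 0.91), and cholesterol synthesis had 0.00 (adjusted p = 0.88). Adipogenic transcription factors had -0.07 (adjusted p = 0.52), with PPARG at 0.07 (adjusted p = 0.78). Steroid hormone receptors and metabolism had 0.06 (adjusted p = 0.41), with ESR1 at 0.33 and HSD11B1 at -0.30 (adjusted p = 0.54 and 0.55). The insulin-like growth factor axis had -0.12 (adjusted p = 0.52), with IGF1 at -0.37 and IGF2 at 0.05 (adjusted p = 0.36 and 0.88), and 1 of the 6 other probe sets of IGF2 went the other way. Insulin signalling had -0.14 (adjusted p = 0.17, and 0.048 without boar replicate 3), thermogenesis -0.13 (median 0.01, adjusted p = 0.57), the cell cycle 0.03 (adjusted p = 0.64), antigen presentation -0.07 (adjusted p = 0.40, and 0.036 without boar replicate 2) and skeletal muscle markers 0.04 (adjusted p = 0.83). In insulin signalling AKT1 and GRB10 had -0.38 and -0.43 (limma adjusted p = 0.083 and 0.097, and 0.035 and 0.028 with the replicate block). Under 5 genes of the granulocyte and mast cell, erythrocyte, skin and nerve lists passed the filter, and these lists were not tested. Of their genes past the filter 1 changed, UCHL1 of the nerve list.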

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

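The comparisons with macrophage markers and with smooth muscle and stromal markers were chosen after those results had been seen, and the latter was compared per pool only after its value over all pools had been seen. The bar on dim skin and gland markers was also set after their values. The gland marker list was written after the skin markers had been tested.

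Outside the comparisons, the array carries 38 control probe sets for pig genes, and in 10 of them all 3 barrow arrays lay above all 3 boar arrays, where chance gives 5%. In 0 of them did all barrow arrays lie below. The 3 control probe sets for an interferon-responsive protein, annotated as RSAD2, were higher in barrows by 1.66 (76.0 ± 4.24 against 282 ± 79.2), 0.99 (77.1 ± 40.3 against 156 ± 25.1) and 0.91 (44.7 ± 6.43 against 97.8 ± 3.02) on the log2 scale (SD, n = 3, exact permutation p = 0.1 each, the smallest 3 against 3 can give). Of 9 GAPDH control probe sets the other 7 were higher by 0.29, 0.22, 0.27, 0.26, 0.20, 0.18 and 0.24, and in 2, at 0.10 and 0.30, the groups overlapped (exact permutation p = 0.4 and 0.2). The 10 thus measure 2 genes and are not independent, which the 5% leaves out of account.

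The 1st pattern is the higher mean of the interferon response list in barrows, with 9 of 20 members past the threshold and a list call that was lost with an estimated correlation (adjusted p = 0.093). Leaving out each array in turn kept the mean log2 difference at or above 0.48, against 0.51 with all arrays, so 1 barrow pool does not carry it. Quantile normalization gave 0.52, but it had little to change and could hardly have lowered the mean. The median log2 difference of all tested probe sets was -0.014 before it and -0.0068 after it. These small medians, rather than the 0.52, argue against a scaling difference between arrays. Macrophage markers had a mean of -0.18, and -0.14 or lower in every fit that left out 1 array. Their sign in those fits was fixed in advance, because the list means of the groups do not overlap. The markers thus show no rise, but their lower mean lost its call with an estimated correlation (camera adjusted p = 0.40). More macrophages are therefore not excluded, and granulocytes and dendritic cells were not tested. A response to castration or to an infection that reached barrows more than boars may stand behind it, and these arrays cannot separate them.

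The 2nd pattern is the lower mean of macrophage and endothelial markers, with 0 of 15 and 1 of 15 members past the threshold. Both calls were lost with an estimated correlation (adjusted p = 0.40 and 0.27), and that of macrophages also with fry (adjusted p = 0.090). Their 30 genes had a mean of -0.18 and 26 smooth muscle and stromal genes one of 0.00, a gap of -0.18 that ran from -0.31 to -0.11 when 1 array was left out (permutation test over genes, p = 0.0035, genes not being independent), but per pool the 2 sets lay -0.29, -0.26 and -0.29 apart in boars and -0.55, -0.22 and -0.62 in barrows (exact permutation p = 0.4). In barrow replicate 2, at the far end of the first principal component, the smooth muscle and stromal genes were low as well (9.92, against 10.27 and 10.26 in the other barrows and 10.11 to 10.18 in boars), so a lower share of all cell types other than adipocytes stays open. For 0 of 2 control genes did the 3'/5' ratios separate the groups, with a mean log2 difference of -0.03 for each. With 3 against 3 arrays this cannot exclude a difference in RNA quality. Barrow replicate 2 had the lowest ratio of all arrays for both actin (1.85) and GAPDH (1.09). Fewer macrophages and endothelial cells, or lower expression in each cell, may also account for the lower markers.

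The 3rd pattern is PIP, whose call was lost without the intensity trend (adjusted p = 0.11), without a filter (adjusted p = 0.052), without boar replicate 1 (adjusted p = 0.098) and without boar replicate 3 (adjusted p = 0.065). Its difference stayed at 2.93 or more when 1 array was left out, although barrow replicate 2 held the highest signal, and was 2.64 with pseudocount 64. Skin tissue stays open: 9 skin markers taken without a filter had a mean difference of 0.073 (SE 0.067 over genes), which is lower than set beforehand for skin, but 7 of them lay below the filter, where a low signal excludes nothing. Gland tissue stays open too: 17 gland epithelium markers, 14 of them below the filter, had a mean of 0.26 (SE 0.16) and ran from -0.61 (AQP5) to 1.73 (KRT19), and either tissue may account for part of it.

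The design allows 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 167 changed probe sets, 101 higher and 66 lower, and the highest of the other 9 gave 0. Each of these 3 counts was reached by 1 of the 10 splits, the real one. With the replicate block the real split gave 338, and the highest of the 3 others that part all pairs gave 0. The other splits hold boar and barrow pools on both sides, so a difference between the groups adds to their spread within sides. Their counts of 0 are therefore no measure of what chance alone would give. For the gene lists, 1 of the 10 splits gave as many as the 10 called, and the highest other split gave 9.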

How the results depend on the processing

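No alternative was added after the data were seen. Of the 37 named genes that passed, 10 kept direction and call under every alternative that gave them a value: C1QTNF3, C4A, CCL4, CES1, CYP2B22, DUSP1, ISG15, LOC100152327, RSAD2 and SLC22A3. None of the 37 changed sign, although with 1 array left out this was fixed in advance, since their groups do not overlap. Calls were lost by 27 without boar replicate 1, 26 without boar replicate 3, 23 without the intensity trend, 18 without barrow replicate 1, 16 without barrow replicate 3 and 13 without a filter, where more probe sets were tested. PIP has no value with pseudocount 1 or in the upper 40%, where UCHL1, COMP, DIRAS3, ZBP1 and the lymphocyte, thermogenesis, cell cycle and skeletal muscle lists have none either. Array detection calls were not used here, so signal over background limits the dim genes by an unknown amount.

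Changed probe sets numbered 167 (101 higher, 66 lower). They numbered 96 (61 and 35) without a filter, 32 (20 and 12) without the intensity trend, 425 (233 and 192) with array weights, 338 (215 and 123) with the replicate block and 337 (191 and 146) at an adjusted p under 0.10. With 1 array left out the count ran from 24 to 291, higher from 16 to 160 and lower from 8 to 131. The replicate block changed no call of a list, lost none of the 37 named calls and gained 20 of the 120 other named genes.

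Called lists numbered 10, 0 with an estimated correlation, 3 with fry (interferon response, complement and endothelial markers) and from 7 to 12 with 1 array left out. Calls were gained by insulin signalling without boar replicate 3 (-0.20), antigen presentation without boar replicate 2 (-0.13) and inflammatory cytokines and chemokines there and in the upper 40% (-0.15 each). Fatty acid synthesis, 0.27, ran from 0.22 to 0.32 with 1 array left out and was 0.36 with the mean of probe sets. Its call was lost with an estimated correlation (adjusted p = 0.44) and fry (adjusted p = 0.13), which do not estimate the mean anew. Fatty acid oxidation, 0.11, lost its call in both (adjusted p = 0.58 and 0.20), under quantile normalization (0.10), array weights (0.091) and the mean of probe sets (0.082), ran from 0.069 to 0.13 with 1 array left out and was 0.20 without a filter (adjusted p = 0.0059). The causes were not tested. The median shift moved the share of higher calls to 66.5% from 60.5%.

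Sign changes were confined to uncalled results, and their cause was not tested. Not all lay near 0 with all arrays, as IGFBP5 (-0.34), MBP (-0.17), insulin signalling (-0.14) and thermogenesis (-0.13) show. With 1 array left out, triacylglycerol synthesis ran from -0.0100 to 0.11, the cell cycle from -0.0054 to 0.045, cholesterol synthesis from -0.023 to 0.034, extracellular matrix from -0.052 to 0.11, skeletal muscle markers from -0.0081 to 0.092, smooth muscle markers from -0.061 to 0.14 and stromal markers from -0.079 to 0.068. Single genes ran from -0.14 to 0.0049 (ADIPOQ), -0.045 to 0.15 (AKT2), -0.31 to 0.52 (COX7A1), -0.11 to 0.033 (HBB), -0.082 to 0.14 (HBM), -0.0058 to 0.092 (IGF2), -0.53 to 0.014 (IGFBP5), -0.011 to 0.14 (JUP), -0.0068 to 0.098 (LPL), -0.16 to 0.23 (MAL), -0.41 to 0.082 (MBP), -0.21 to 0.15 (MCT7) and -0.099 to 0.068 (S100B). Without a filter insulin signalling was 0.025, thermogenesis 0.014, the cell cycle -0.082 and stromal markers 0.015. In the upper 40% extracellular matrix was -0.0020, smooth muscle -0.020 and stromal markers 0.012. Extracellular matrix was -0.0030 under quantile normalization. With array weights cholesterol synthesis was -0.0025, stromal markers 0.024, COX7A1 -0.24, MCT7 0.028 and MAL 0.083. With the mean of probe sets extracellular matrix was -0.0089, smooth muscle -0.0082, STAT5B -0.0077, MBP 0.099 and PNPLA2 0.044.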

Other observations

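The elongase ELOVL6 differed between its probe sets. The brightest, at 18425 ± 675 in boars and 21423 ± 1365 in barrows, had a log2 difference of 0.22, and the 3 dimmer ones had 0.81 to 0.96.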
